A study of Homo sapiens with 6 samples.

How the data were processed

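RNA was measured in 6 libraries labelled as T24 bladder cancer cells, grown in RPMI medium with serum and transfected by lipofection with an empty pcDNA3.1 plasmid (Vector, n = 3) or with the plasmid carrying LINC00665 (n = 3). Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes, HISAT2 2.0.4 and the genome build hg38 were used, with no role stated. The counting tool, the gene annotation and the use of strand are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies therefore cannot be told apart with certainty.

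The authors deposited 1 table of 20289 genes with an expected count per gene and library, per the file headers, not normalised and with 88.3 to 89.4% of the values whole to the decimals given. The same deposited table holds FPKM values, normalised by the authors for gene length and library size, per the file headers. Of the identifiers, 20171 were found in GENCODE v29 (GRCh38, the same assembly as hg38), 19783 of them protein-coding, and 583 genes had no symbol. LINC00665 was not among them and its level was not analysed here, nor were annotated terms. Groups and replicate numbers came from the labels, which name 3 independent experiments.

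Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr, scaled by the trimmed mean of M-values and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with no covariate. The adjusted p is Benjamini-Hochberg over the 13552 genes tested, with a threshold of 0.05 and no fold minimum. The standard error of a log2 fold change was computed from the fold change and the F statistic. CPM values are given as mean ± SD over 3 libraries. For a group at 0 counts the fold is a lower bound against 3 counts over the whole group, and for 1 to 3 counts the ratio is given with an exact 95% binomial interval. Bounds and intervals cover counting error only, as the reads carry no molecular identifiers. Exact permutation tests of single genes were two-sided.

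The 32 gene lists were fixed before the data were examined. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Named genes were chosen by a rule fixed at the same time. It took up to 12 genes per direction with the largest absolute log2 fold change, among those past the threshold, with at least 1 in absolute log2 fold change, groups that did not overlap, a mean of at least 5 CPM and an official symbol. It also took the 4 members of each list with the smallest p, and RAB27B, HGF, MYC, MET, VEGFC and VEGFA. Other genes named were chosen after their values were seen. Of the genes selected in this way, those that matter most are given with their values, and some are not reported here.

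Alternatives were size factors, other filters on low counts, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), the replicate number as a block, other thresholds, and leaving out each library. Total-count scaling, libraries thinned to the smallest total and genes at a mean of 1 CPM or more in both groups were added after the data were seen. Library pairs of the same label differed by more than sampling noise, with chi-square per degree of freedom from 9.85 to 116, so no library was counted as a duplicate of another. A check for mixed-up samples found 3 of 6 libraries that did not match the labelled line. The 46 genes used in or related to that check took part in the fit and are not reported. No fit without those 3 libraries was possible, because no comparison between the labels would be left.

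The count test was tested on simulated data with the 13552 genes and dispersions of this comparison and 200 changed genes. It recovered 46% of genes changed 2-fold and 94% of those changed 4-fold, and 6.67% of its calls were false. The simulation used 1 dispersion per gene for both labels and few changed genes. In the data 63.5% of tested genes changed, and the biological coefficient of variation was 28.7% under the Vector and 12.8% under the LINC00665 label. The simulated rates therefore need not carry over to the data. Of 1 simulated changed list and 20 unchanged lists, camera called 1 and 0. Depth was 17289788 to 22725687 expected counts per library, and 3 counts over the 3 libraries of a group set the limit of detection. Figures were drawn with matplotlib 3.10.9.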

Results

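Gene expression was measured by RNA sequencing in 6 libraries labelled as T24 cells, an established human bladder cancer cell line, after transfection with a plasmid. In 3 libraries the plasmid is labelled as the empty vector (Vector) and in 3 as carrying LINC00665, a long intergenic non-coding RNA, for overexpression. The labels state that the libraries came from 3 independent experiments. The expected counts summed to 20023417, 17289788 and 18240943 in the libraries labelled Vector 1 to 3 and to 22725687, 20736693 and 19114096 in those labelled LINC00665 1 to 3. Between 14190 and 14291 genes had at least 1 count in the former and between 15457 and 15658 in the latter. The single comparison of the design asks which transcripts differ when LINC00665 is overexpressed, and the stated interest is its mechanism in lymph node metastasis of bladder cancer.

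LINC00665 lies on chromosome 19 at positions 36313067 to 36331718 of GRCh38, on the minus strand, and is annotated as a lincRNA. Its own level was not analysed here, since 0 of the table's genes carry its identifier, so the overexpression was not checked from these values. In a check for mixed-up samples, 3 of the 6 libraries did not match the line named in their labels. Groups are therefore named by their labels throughout, and directions are given as libraries labelled LINC00665 relative to libraries labelled Vector.

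The libraries of the 2 labels differed across most of the measured transcriptome. Most tested members of the epithelial, basal and luminal urothelial, NF-kB and heat shock lists were higher under the LINC00665 label. The counts were 18 of 25, 17 of 19, 10 of 12, 22 of 32 and 13 of 20 in that order. None of these lists was called by camera with an estimated correlation. Single genes reached ratios of 1170 (HSPA6), 1300 (TP63), 2630 (KRT19) and 3140 (IL1A), over only 5 to 63 counts in all under the Vector label. The heat shock list's median log2 fold change was 0.83. PAX2, HAVCR1 and KCNJ16 were far more abundant under the Vector label. Of 13552 genes tested, 8611 (63.5%) changed by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, 4634 higher and 3977 lower. An absolute log2 fold change of at least 1 was reached by 5691 of these genes, 3535 higher and 2156 lower. The median absolute log2 fold change of the changed genes was 1.36. The 3 libraries of one label lay entirely above the 3 of the other for 9518 genes (70.2%), against 10% by chance.

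A total of 416 genes had a mean CPM (expected counts scaled to library size) of at least 5 under the LINC00665 label and under 0.1 under the Vector label, and 37 genes showed the opposite. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.659 to 0.68 between libraries of different labels, 0.967 to 0.982 among those labelled Vector and 0.985 to 0.99 among those labelled LINC00665. The first principal component held 93.2% of the variance. The biological coefficient of variation was 28.7% within the Vector label and 12.8% within the LINC00665 label. For each of the 151 named genes that were tested, the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries can give; the naming rule favours such genes, so this is no further evidence of a difference.

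**Figure D1:**
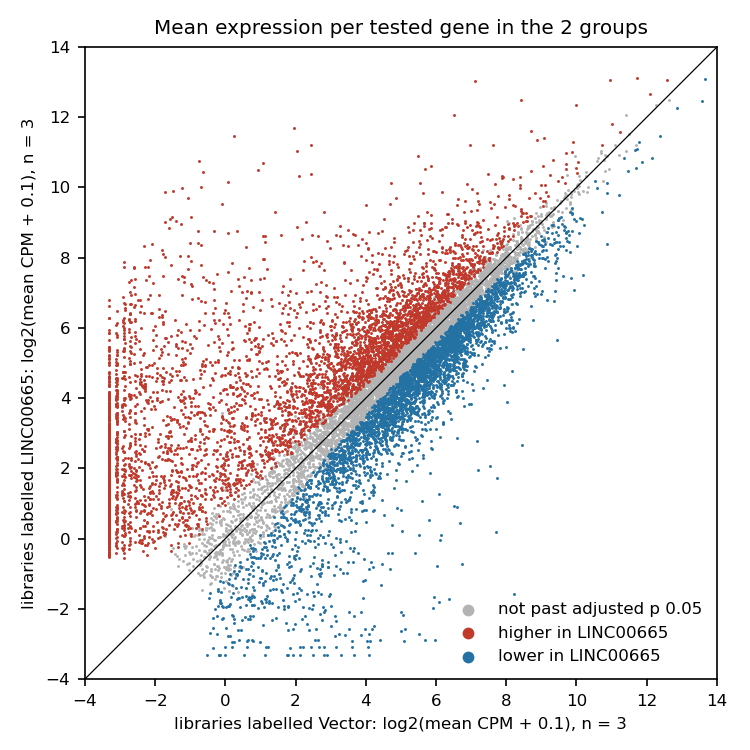
Mean expression of each tested gene in the libraries labelled Vector (x axis) and LINC00665 (y axis), as log2(mean CPM + 0.1) with 3 libraries per group, coloured by edgeR call; 46 genes that are not reported are not drawn. Of 13552 genes tested, 4634 were higher and 3977 lower under the LINC00665 label.

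The 12 increases with the largest fitted log2 fold changes were in genes with 0 counts in all 3 libraries labelled Vector. Their folds are known as lower bounds, which the measured ratio of 4550 for KRT17 exceeds, so these genes are not shown to have risen most. SPOCK1, a secreted proteoglycan, stood at 111 ± 14.2 CPM (SD, n = 3) under the LINC00665 label, at least 2170-fold higher. TMPRSS2, a transmembrane serine protease, reached 78.4 ± 16.4 CPM (at least 1550-fold higher), and GRHL2, a transcription factor of epithelial cells, 77.1 ± 5.01 CPM (at least 1520-fold higher). The growth factor BMP2 was at 58.3 ± 0.631 CPM (at least 1140-fold higher) and the calcium-binding protein S100A8 at 41.7 ± 12.1 CPM (at least 826-fold higher). HEPHL1, TMEM30B, SERPINB9, CDC42EP5, CTSF, FAT3 and MAGED4 completed the 12, with lower bounds from 840-fold for MAGED4 to 1910-fold for HEPHL1. MAGED4 has a near-identical copy, MAGED4B, so its value is uncertain. Each bound sets the Vector label at 3 counts over the group.

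The 12 decreases with the largest fitted log2 fold changes included ion channel, receptor and transcription factor genes. KLHL4 had 0 counts under the LINC00665 label and was at least 327-fold lower. KCNJ16, a potassium channel subunit, fell from 62.8 ± 21.8 CPM to 2 counts in all, a ratio of 1830 with a 95% counting interval of 507 to 15100. CD40, a receptor of the tumour necrosis factor receptor family, fell from 51.2 ± 10.9 CPM to 2 counts, a ratio of 1510 (417 to 12500). WSCD1 fell from 299 ± 15.1 to 0.238 ± 0.0828 CPM, with a log2 fold change of -10.26 (SE 0.25, adjusted p = 1e-07). The kidney transcription factor PAX2 fell from 32.1 ± 10.8 to 0.062 ± 0.107 CPM and ALDH1A1, an aldehyde dehydrogenase of retinoic acid synthesis, from 34.7 ± 9.01 to 0.0669 ± 0.0584 CPM. WDR72, DCDC2, NAP1L3, HAVCR1 and BEND4 were also among the 12. They had 1 to 3 counts in all under the LINC00665 label, and their ratios, with 95% counting intervals such as 274 to 8180 for WDR72 and 177 to 5300 for HAVCR1, do not rank them.

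Among the genes of the study field, MET, the receptor of hepatocyte growth factor, rose from 88.5 ± 37.5 to 503 ± 105 CPM, a log2 fold change of 2.51 (SE 0.35, edgeR adjusted p = 0.00036). VEGFC, the main lymphangiogenic growth factor, rose from 2.43 ± 0.937 to 57.4 ± 2.39 CPM (log2 fold change 4.56, SE 0.29, adjusted p = 4.5e-06). VEGFA rose from 83.7 ± 31.9 to 314 ± 22.1 CPM, by 1.91 on the log2 scale (SE 0.28, adjusted p = 0.00049). MYC rose from 119 ± 34.7 to 472 ± 41.4 CPM (1.99, SE 0.22, adjusted p = 9.4e-05). RAB27B, a small GTPase of exosome secretion, rose from 2.43 ± 1.3 to 9.99 ± 3.36 CPM (2.03, SE 0.44, adjusted p = 0.0039). Line and plasmid cannot be separated in this design, so none of these differences can be credited to LINC00665. HGF had 0 counts under the Vector label and 1 count under the LINC00665 label, below 3 counts in both, so no difference was detectable at this depth. In GRCh38, RAB27B lies on chromosome 18 at 54717860 to 54895516, MET on chromosome 7 at 116672390 to 116798386 and VEGFC on chromosome 4 at 176683538 to 176792727.

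**Figure D2:**
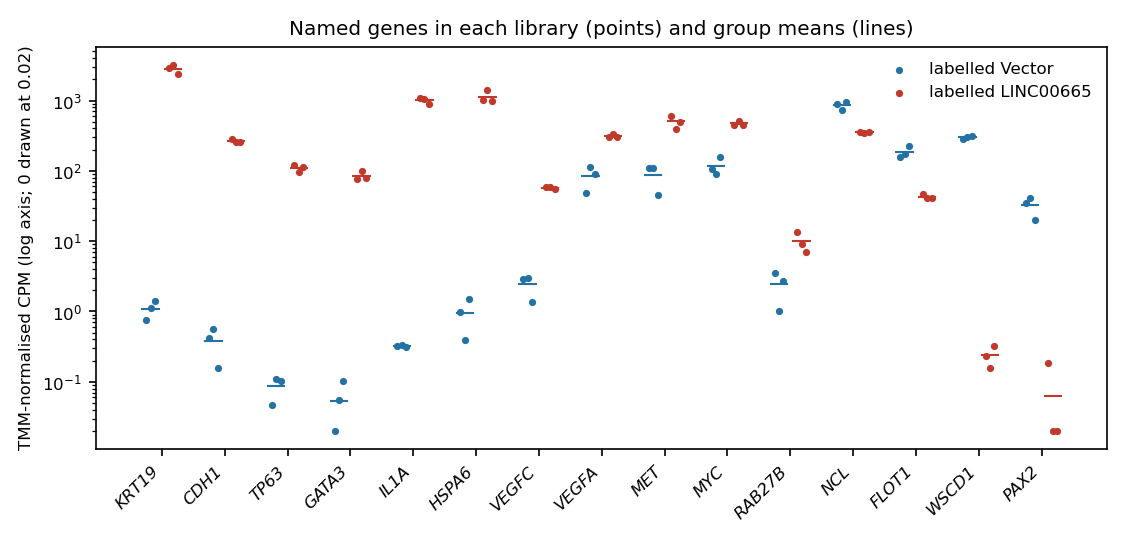
CPM normalised by the trimmed mean of M-values (log axis, 0 drawn at 0.02) of 15 named genes in each of the 6 libraries; points are libraries and lines are group means. The 3 libraries of one label lie above the 3 of the other for each gene drawn, with KRT19 at 1.08 CPM under the Vector label and 2810 CPM under the LINC00665 label.

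Secreted lymphangiogenic and angiogenic factors were mostly higher under the LINC00665 label. Of 21 tested members, 15 rose, 3 fell and 3 did not pass over all genes, and 16 rose and 3 fell when adjusted over the list alone. Members with the smallest p included PDGFA (0.205 to 52.6 CPM), the vasodilator peptide ADM (9.57 to 476 CPM) and PTGS2, which makes prostaglandins (15.9 to 722 CPM). The list's median log2 fold change was 2.45, with a camera adjusted p of 0.018 and adjusted p = 0.34 with an estimated correlation.

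Small extracellular vesicle secretion genes moved both ways, as did all tested genes (4634 higher and 3977 lower of 13552). Of 39 members, 14 rose, 13 fell and 12 did not pass, counts that were also found when adjusted over the list alone. The synaptotagmin-like SYTL1 rose from 0.0656 to 16.8 CPM and the GTPase RALA from 24.6 to 79.5 CPM, while FLOT1, a lipid raft protein, fell from 183 to 42.9 CPM and the ATPase VPS4A from 145 to 56.1 CPM. The list as a whole was not called (camera adjusted p = 0.74). The HGF-MET list was not called either by camera (adjusted p = 0.6), though it was by fry's directional test (adjusted p = 0.00015, range over its alternatives 0.00015 to 0.86), with 8 of 17 members higher and 3 lower over all genes, and 8 higher and 4 lower when adjusted over the list alone. Its serine protease ST14 rose from 0.119 to 214 CPM and its inhibitor SPINT1 from 0.951 to 417 CPM, whereas the adaptor SHC1 fell from 926 to 172 CPM.

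Most tested genes of the epithelial and urothelial lists were higher under the LINC00665 label. In the epithelial adhesion list 18 of 25 members rose and 0 fell, over all genes and when adjusted over the list alone. KRT19 rose from 1.08 ± 0.326 to 2810 ± 387 CPM and E-cadherin, CDH1, from 0.377 ± 0.203 to 266 ± 15.9 CPM. The list's median was 4.54 (camera adjusted p = 4.4e-05, and adjusted p = 0.14 with an estimated correlation). Basal urothelial genes rose in 17 of 19 cases and fell in 0 (18 and 0 when adjusted over the list alone), with TP63, the transcription factor of basal epithelium, at 0.0871 ± 0.0352 and 110 ± 13.5 CPM. Their median was 9.19, or 8.72 with genes at 0 counts set at their bound (camera adjusted p = 4e-08, and adjusted p = 0.14 with an estimated correlation). Luminal urothelial genes rose in 10 of 12 cases and fell in 0 on both adjustments, that is also when adjusted over the list alone. The luminal regulator PPARG rose from 1.84 to 130 CPM, and GATA3 from 3 counts in all to 84.9 CPM, a ratio of 1660 with a 95% counting interval of 566 to 8030. The luminal median was 5.24 (camera adjusted p = 6e-04, and adjusted p = 0.14 with an estimated correlation). Of 18 luminal genes, 6 were not tested, among them UPK1A, which stood lower under the LINC00665 label, at 0.584 and 0.0359 CPM (33 and 2 counts). The filter on low counts limits these lists, since 10 of the 18 epithelial, 13 of the 17 basal and 5 of the 10 luminal genes that rose would not have passed it in the libraries labelled Vector alone, which ties their direction to it. With only genes at 1 CPM or more in all 6 libraries, the camera adjusted p was 0.038 for the epithelial, 0.0011 for the basal and 0.012 for the luminal list. These lists separate the same libraries whose correlation across genes was 0.659 to 0.68 between labels.

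Mesenchymal and invasion genes also rose on balance, in 17 of 30 cases with 5 falls (18 and 5 when adjusted over the list alone). The matrix metalloproteinases MMP14 (1.15 to 432 CPM) and MMP1 (4.16 to 1290 CPM) and the transcription factor SNAI2 (0.107 to 164 CPM) rose. ZEB1 and vimentin, VIM, both known from mesenchymal cells, fell from 15.6 to 0.0665 and from 1880 to 333 CPM; this pair was chosen after its values were seen. The list's median was 1.74 (camera adjusted p = 0.0038, and adjusted p = 0.14 with an estimated correlation). Markers of other cell types were tested only where they passed the filter on low counts, which 8 of 15 fibroblast, 5 of 17 endothelial and 4 of 17 leukocyte markers did. Of the fibroblast markers tested, 7 rose and 0 fell (7 and 0 when adjusted over the list alone), with THY1 at 165 CPM against 3 counts in all. FAP had 0 counts under the Vector label, and THY1, PDGFRB, COL1A2 and COL6A3 stood at 0.0543 to 0.351 CPM, so their direction is tied to the filter, while LUM, not tested, was at 0.142 and 0.173 CPM. Their median was 4.78 (camera adjusted p = 0.0014, and adjusted p = 0.14 with an estimated correlation). The 5 tested endothelial markers rose, also when adjusted over the list alone, PDPN at least 150-fold and KDR at least 103-fold. PDPN, KDR, FLT1 and VWF had 0 counts under the Vector label and so passed the filter by their level under the LINC00665 label alone. This fixes their direction. PECAM1, at 0.317 CPM under the Vector label, would not have passed there either, so the direction of all 5 is tied to the filter. CDH5, not tested, was at 0.436 and 0.484 CPM. The median was 9.7, or 6.69 at the bound (camera adjusted p = 0.0014, and adjusted p = 0.2 with an estimated correlation). The 4 tested leukocyte markers, CD74, CSF1R, CD14 and CD68, rose, also when adjusted over the list alone, with CD74 at 0.169 and 122 CPM. Under the Vector label CSF1R had 0 counts, and CD74 and CD14 stood at 0.169 and 0.284 CPM, so their direction is likewise tied to the filter, while PTPRC had 1 and 0 counts and was not tested. Their median was 5.82, or 4.31 at the bound (camera adjusted p = 0.028, and adjusted p = 0.25 with an estimated correlation). CD68 was no longer past the threshold with the replicate block (edgeR adjusted p = 0.06), without Vector 1 (0.052) or without LINC00665 2 (0.099). With no filter on low counts the leukocyte list was not called (camera adjusted p = 0.27, median 0.99).

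Most tested inflammatory, interferon-stimulated and growth factor response genes were higher under the LINC00665 label. In the NF-kB list 22 of 32 members rose and 1 fell, over all genes and when adjusted over the list alone. The cytokine IL1A rose from 0.323 ± 0.0117 to 1010 ± 99.9 CPM, IL1B from 1.8 to 1430 CPM and the iron-binding lipocalin LCN2 from 3.81 to 3300 CPM. The median was 2.54 (camera adjusted p = 0.00018, and adjusted p = 0.64 with an estimated correlation). Interferon-stimulated genes rose in 32 of 47 cases and fell in 5 (33 and 5 when adjusted over the list alone), among them MX1 from 0.771 to 32.9 CPM and TRIM22 from 0.0871 to 17.4 CPM. The median was 2.4 (camera adjusted p = 0.00036, and adjusted p = 0.55 with an estimated correlation). Immediate early and ERK output genes rose in 23 of 31 cases and fell in 1, on both adjustments, that is also when adjusted over the list alone. The phosphatase DUSP4 rose from 0.408 to 571 CPM, FOS from 2.88 to 397 CPM and EGR1 from 29.1 to 825 CPM, with a list median of 2.14 (camera adjusted p = 0.00028, and adjusted p = 0.53 with an estimated correlation).

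Among stress response genes, more rose than fell. Of 20 cytosolic heat shock genes, 13 rose and 2 fell, over all genes and when adjusted over the list alone. HSPA6, an inducible chaperone, rose from 0.956 ± 0.556 to 1140 ± 220 CPM and its co-chaperone DNAJB1 from 90.9 ± 36.4 to 4300 ± 515 CPM. HSPA1B rose from 137 to 8370 CPM and the nearly identical HSPA1A fell from 258 to 96.8 CPM (log2 fold change -1.41, adjusted p = 0.00053); both values are uncertain, because reads of one can be assigned to the other, and both are in the counts above. The median was 0.83 (camera adjusted p = 0.029, and adjusted p = 0.53 with an estimated correlation). Unfolded protein response and ATF4 targets rose in 21 of 37 cases and fell in 2, on both adjustments, that is also when adjusted over the list alone, with the chaperone HSPA5 at 1010 ± 259 and 5200 ± 362 CPM and PPP1R15A at 125 and 2380 CPM. The median was 0.96 (camera adjusted p = 0.0019, and adjusted p = 0.64 with an estimated correlation).

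More WNT and YAP-TAZ targets rose than fell. WNT targets rose in 12 of 18 cases and fell in 3, also when adjusted over the list alone, with BMP4 at 0.434 and 54.1 CPM and WNT5A at 0.181 and 37.7 CPM. The median was 2.21 (camera adjusted p = 0.028, and adjusted p = 0.25 with an estimated correlation). YAP-TAZ targets rose in 13 of 24 cases and fell in 2 (14 and 2 when adjusted over the list alone), with AJUBA at 16.3 and 171 CPM and F3 at 5.84 and 238 CPM. The median was 0.89 (camera adjusted p = 0.028, and adjusted p = 0.53 with an estimated correlation). With only genes at 1 CPM or more in all 6 libraries, the WNT list was no longer called (adjusted p = 0.58, range over its alternatives 1.6e-06 to 0.58), nor were the leukocyte list (0.53, range 3.4e-06 to 0.53), the MYC list (0.057) and the mitotic list (0.17).

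Of 41 nuclear-encoded oxidative phosphorylation genes 24 were lower under the LINC00665 label, while most of the MYC and mitotic genes were not past the threshold as lower. Of 30 genes in the MYC list, 12 fell, 3 rose and 15 did not pass, also when adjusted over the list alone; MYC itself was among those that rose. The nucleolar protein NCL fell from 851 ± 112 to 354 ± 7.5 CPM and ODC1, of polyamine synthesis, from 416 ± 57.5 to 157 ± 12.4 CPM. The median was -0.51 (camera adjusted p = 0.028, and adjusted p = 0.69 with an estimated correlation). Mitotic genes fell in 16 of 40 cases, rose in 5 and did not pass in 19 (14 falls and 5 rises when adjusted over the list alone), with the kinesin KIF11 at 101 and 41.6 CPM and cyclin B1, CCNB1, at 298 and 155 CPM. The median was -0.38 (camera adjusted p = 0.028, and adjusted p = 0.69 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 24 of 41 cases and rose in 3, also when adjusted over the list alone, among them NDUFS1 (191 to 72.8 CPM) and SDHC (156 to 80.2 CPM). The median was -0.51 (camera adjusted p = 0.0014, and adjusted p = 0.64 with an estimated correlation). Without the library labelled Vector 3, the camera adjusted p was 0.051 for the MYC list (range over its alternatives 0.0043 to 0.69) and 0.06 for the mitotic list (range 0.0042 to 0.69), so neither was called. The same 2 lists were also lost with genes at 1 CPM or more in all 6 libraries (0.057 and 0.17) and with fry's directional test (0.098 and 0.087).

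**Figure D3:**
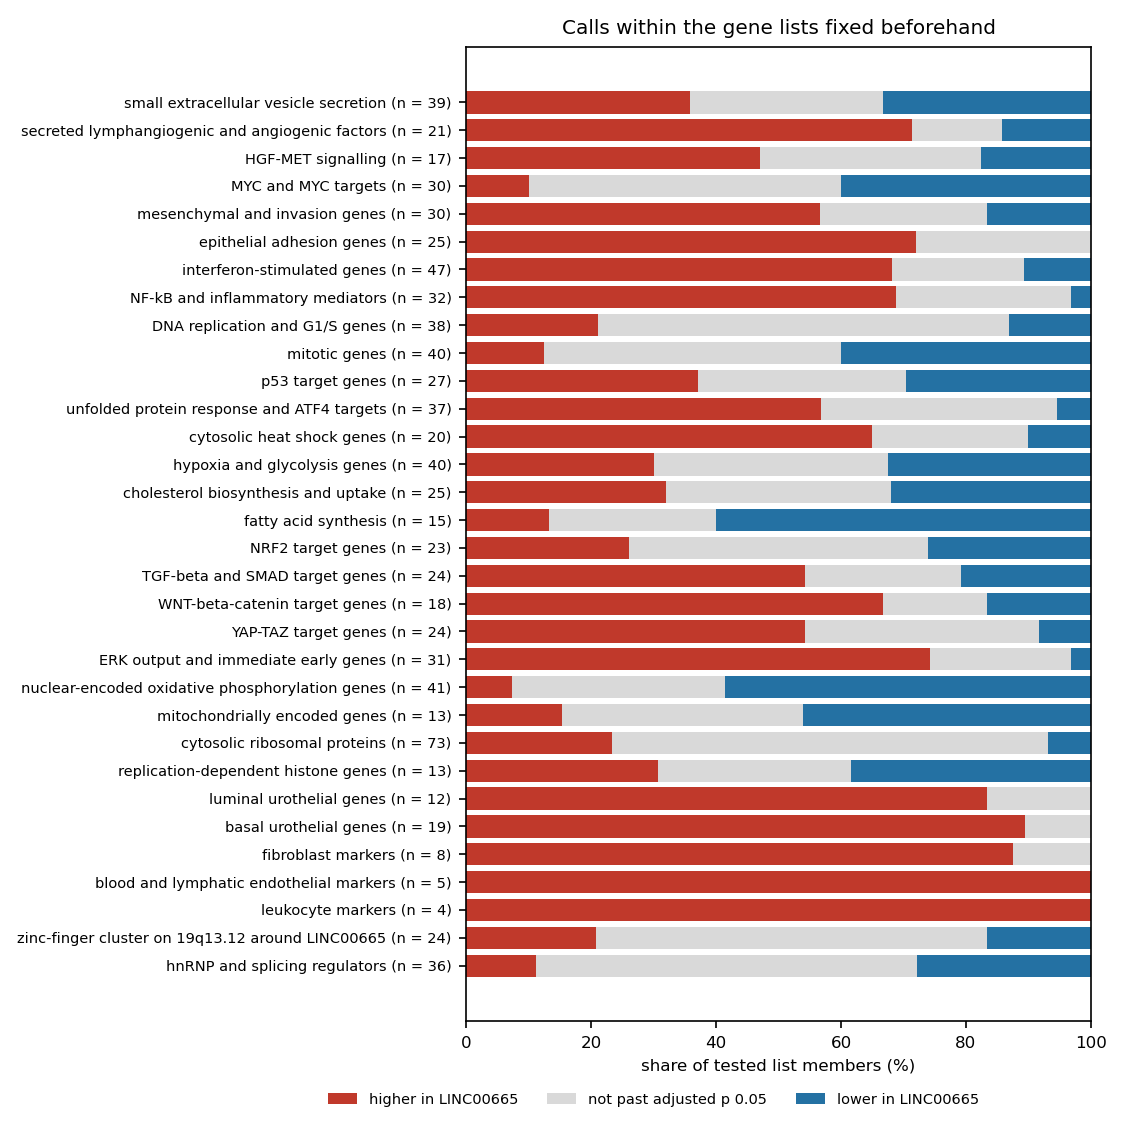
Share of tested members of each of 32 gene lists (x axis, percent) that were higher, lower or not past an adjusted p of 0.05 under the LINC00665 label by edgeR; n is the number of tested members. All 19 basal urothelial members were either higher (17) or not past the threshold, while 24 of 41 oxidative phosphorylation members were lower.

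Further lists were not called by camera in the main test. Their counts, here and in the next paragraph, stand against 4634 higher and 3977 lower of all 13552 tested genes. Counts near those shares say nothing particular about a list. TGF-beta and SMAD targets had 13 members higher and 5 lower of 24 (14 and 5 when adjusted over the list alone, camera adjusted p = 0.066), with SMAD7 at 5.18 and 49.6 CPM. This list was called under several alternatives, such as limma-voom (camera adjusted p = 0.044, range over its alternatives 0.00011 to 0.41). Fatty acid synthesis genes had 2 higher and 9 lower of 15 on both adjustments, that is also when adjusted over the list alone (adjusted p = 0.13), FADS2 rising from 16.8 to 305 CPM and ACLY falling from 807 to 445 CPM. Hypoxia and glycolysis genes numbered 12 higher and 13 lower of 40, also when adjusted over the list alone (adjusted p = 0.74), with CA9 at 0.707 and 74.3 CPM. For p53 targets the counts were 10 higher and 8 lower of 27, and 10 and 9 when adjusted over the list alone (adjusted p = 0.74). NRF2 targets had 6 higher and 6 lower of 23, also when adjusted over the list alone (adjusted p = 0.55), with NQO1 falling from 786 to 177 CPM. Cholesterol genes had 8 higher and 8 lower of 25 (9 and 8 when adjusted over the list alone, adjusted p = 0.88, and 0.049 with fry's directional test, range over its alternatives 0.049 to 0.99), with FDFT1, the squalene synthase, rising from 154 ± 38.3 to 466 ± 59.1 CPM.

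DNA replication and G1/S genes had 8 members higher and 5 lower of 38 (7 and 5 when adjusted over the list alone, camera adjusted p = 0.91), and cytosolic ribosomal proteins 17 higher and 5 lower of 73 (14 and 2 when adjusted over the list alone, adjusted p = 0.91). Splicing regulators had 4 higher and 10 lower of 36 (4 and 9 when adjusted over the list alone, adjusted p = 0.13), a list that was called without the library labelled Vector 2 (adjusted p = 0.026, range over its alternatives 0.026 to 0.81). Mitochondrially encoded genes had 2 higher and 6 lower of 13 (2 and 7 when adjusted over the list alone, adjusted p = 0.15), with MT-CYB at 3340 and 1500 CPM. Histone genes had 4 higher and 5 lower of 13, also when adjusted over the list alone (adjusted p = 0.74). The zinc-finger genes around the LINC00665 locus on 19q13.12 had 5 higher and 4 lower of 24 (4 and 3 when adjusted over the list alone, adjusted p = 0.87), with ZFP82 at 3.1 and 8.77 CPM.

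In all, camera called 18 of the 32 lists, 15 up and 3 down, and with an estimated correlation 0 of them; fry's directional test called 19. Fry's mixed test called 32, and neither fry p compares a list with other genes. Median, mean and camera direction differed in sign for the small vesicle, p53, hypoxia, cholesterol, NRF2, G1/S and zinc-finger lists. Scaling to total counts shifted the median log2 fold change of all tested genes by -0.16. It left the sign of the median of each of the 18 called lists in place, as did size factors and FPKM values, while the medians of the small vesicle, G1/S, cholesterol, ribosomal and zinc-finger lists changed sign. Medians further from 0 than that shift could hardly change sign under total-count scaling, so its outcome for the called lists was fixed in advance. The medians of some called lists depended on the filter and the unit. Of the genes that rose, 13 of 32 interferon-stimulated and 7 of 12 WNT genes would not have passed the filter in the libraries labelled Vector alone. With only genes at 1 CPM or more in all 6 libraries, the median was 0.27 for WNT targets, 0.79 for epithelial adhesion, 1.01 for interferon-stimulated, 1.09 for mesenchymal, 2.5 for luminal, 4.57 for basal and 0.92 for leukocyte genes. On log2(FPKM + 1) values it was 0.54 for heat shock, 0.98 for interferon-stimulated, 1.89 for leukocyte, 1.91 for fibroblast, 2.06 for luminal, 2.23 for endothelial, 2.78 for epithelial and 4.91 for basal genes, a scale that understates the change of low genes. With no filter it was 4.21 for endothelial and 0.99 for leukocyte markers.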

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

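Total-count scaling, thinning and the restriction to genes at 1 CPM in both groups were chosen after seeing the data. The number of changed genes, 8611 by edgeR, was 8595 with size factors, 8944 with total-count scaling, 9232 with no filter, 6257 with genes at 1 CPM in all 6 libraries, 9286 with DESeq2, 8643 with limma-voom, 7791 with FPKM and 6448 with a mean of 1 CPM in both groups. Leaving out 1 library gave 7458 to 9258. An adjusted p below 0.01 gave 6774 genes. With a log2 fold minimum of 1 the count was 5691 and that of lower genes 2156, since fewer genes can pass. The share of higher genes was 53.8%, and 46.7% with total-count scaling.

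With the replicate number as a block, 7924 genes changed, 7861 of them also changed without it in the same direction. Deviations from the group mean correlated by 0.152, -0.132 and -0.154 for the libraries sharing numbers 1, 2 and 3. For unlike numbers the correlation reached 0.207. The deviations gave no sign of pairing by number, but with 3 libraries per label they cannot exclude it.

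Of 2270 values of 151 named genes under the alternatives, 2267 kept direction and side of the threshold, 0 reversed and 3 were no longer past it. All 3 were CD68, with adjusted p of 0.06 under the block, 0.052 without Vector 1 and 0.099 without LINC00665 2 (range over its alternatives 0.0063 to 0.099). The naming rule favours genes with large differences, so the stability of these 151 genes was largely built in. Of 511 values of gene lists, 474 kept their side, 28 lost the call, 9 gained one and 0 reversed. With an estimated correlation 0 lists were called, against 18. The estimate was below the preset 0.01 for the luminal (-0.037), fibroblast (-0.015), WNT (-0.045), leukocyte (-0.21) and mesenchymal (-0.00093) lists. These lists lost their calls without a stronger correlation among their own members. Other called lists had higher estimates, up to 0.64 for the NF-kB list. The cause of the lost calls was not tested. The lowest camera adjusted p with an estimated correlation was 0.14, and the basal list (4e-08 with the preset) stood there too. A lost call in that setting therefore does not set one list apart from another. The endothelial list was lost with FPKM (adjusted p = 0.14, range 2.4e-06 to 0.2), and the leukocyte list with no filter (0.27, range 3.4e-06 to 0.53); the cause was not tested. TGF-beta targets, not called, were called with fry (0.00011), genes at 1 CPM in all 6 libraries (0.023), FPKM (0.035), total-count scaling (0.043), limma-voom (0.044) and without LINC00665 3 (0.046), over a range of 0.00011 to 0.41. Camera was not run with DESeq2, the endothelial list held no gene at 1 CPM in all 6 libraries, and pseudocount alternatives did not apply to counts. Depth limits genes under 3 counts in both groups, such as HGF.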

Other observations

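The families and cell-origin markers here, and the tests of chance, depth, the plasmid and renal tubule origin, were chosen after the result was seen; the test of neighbouring genes was written down before its result.

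Of 14 gene families tested, camera called 10 with its preset correlation, and with an estimated correlation none passed (adjusted p = 0.14 to 0.79). Among the families named here, keratins, collagens, integrins and proteasome subunits (PSMB9) share members with the fixed lists, so their values partly repeat those results. Of 17 keratins 16 rose and 0 fell, with KRT7, in none of the lists, rising from 5.29 to 2380 CPM. Of 30 collagens 20 rose and 2 fell, COL7A1 rising from 2.05 to 247 CPM and COL18A1 falling from 696 to 49.9 CPM. HOXA genes rose in 10 of 11 cases and HOXD genes in 7 of 8, with HOXA9 at 3.04 and 95.2 CPM, whereas HOXC genes fell in 3 of 5 and rose in 0, HOXC9 from 6.39 to 0.444 CPM. HOXB genes went both ways and were not called (6 higher and 2 lower of 9, camera adjusted p = 0.19), and neither were beta protocadherins (2 higher and 5 lower of 9, adjusted p = 0.19) and genes whose symbols begin with ITGA or ITGB, mostly integrins (10 higher and 8 lower of 22, adjusted p = 0.77). Gamma protocadherins, which share exons so that single members are uncertain, fell in 11 of 17 cases and rose in 3. The median log2 fold changes were 9.2 for keratins, 3.77 for collagens, 2.05 for HOXA, 5.36 for HOXD, -3.8 for HOXC and -2.57 for gamma protocadherins. Size factors and total-count scaling left these signs in place, an outcome that medians this far from 0 fixed in advance. Camera adjusted p over 14 families was 2.3e-07, 0.00044, 0.0012, 0.0061, 0.032 and 0.011 in that order, and with an estimated correlation it was adjusted p = 0.17, 0.14, 0.17, 0.17, 0.17 and 0.39. The proteasome family was not called (3 higher and 5 lower of 17, camera adjusted p = 0.23). Within it the immunoproteasome subunits PSMB8 and PSMB9 rose from 8.06 to 55.5 and from 2.85 to 23.7 CPM, while PSMB6 fell from 143 to 56.4 CPM.

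In the number of changed genes, the real grouping gave 8611 and the highest of the other splits of the 6 libraries into 3 and 3 gave 0. Only 1 of the 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05.

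The labels stood apart across the transcriptome, with 416 genes present under the LINC00665 label and nearly absent under the other. Unequal depth is argued against, since 8504 genes still changed with each library thinned to the smallest total. A response to the plasmid within 1 line is argued against as the whole cause, since 3 of the 6 libraries did not match the labelled line. That value was already known, so this restates the check and is no separate test. Another explanation resting on the same value, libraries that do not hold the labelled line, was dropped after its result was seen. Cells with different genomes under the 2 labels are a candidate explanation: the SD of the median log2 fold change over 124 windows of at least 100 neighbouring genes (up to 198 at chromosome ends) was 0.4, against a mean of 0.14 and a maximum of 0.176 in 1000 shuffles of gene positions, although neighbouring genes that are regulated together would also raise it. The plasmid as part of the cause stays open and untested, because line and plasmid could not be separated in this design.

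The kidney genes PAX2, HAVCR1 and KCNJ16 were among the 12 genes named for their decrease. PAX8 stood at 262 ± 63.6 CPM against 14.7 ± 0.695 CPM, while LHX1 went the other way, at 0.337 and 18.5 CPM. Cells of renal tubule origin in these libraries are a possible explanation that the test leaves open: 7 of 18 markers were at 1 CPM or more in all 3 libraries labelled Vector and 2 in those labelled LINC00665. In the same Vector-labelled libraries 6 of 20 basal and 6 of 18 luminal urothelial markers reached that level, against 19 and 12 under the LINC00665 label. Both the markers and the level of at least 9 set for the test were chosen with the values known, so the count decides nothing. Neither the renal nor the urothelial marker counts show which of the 2 labels holds the line named in the labels.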
